A study of Mus musculus with 4 samples.

How the data were processed

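Lungs of C57BL/6 mice bearing HKP1 tumours, mock-treated (0 Gy) or given 4 Gy on 3 days in a row, were pooled from 4 mice per treatment, per the labels' protocols, sorted into CD45-negative and CD45-positive live cells and profiled with 10x Genomics 3′ chemistry. There were 4 libraries, 1 for each dose and sort, each taken into its group from the labels. The authors deposited 1 table per library with log2 values, cells by 20640 genes. STAR, Partek and Seurat and the build mm10 are named in the submitters' processing notes, without role or version, and what each did is not given in the sources used here. The deposited log2 values were tested on the tables: in each cell 2 to the power of the value, less 1, summed to the total that CPM has by definition, and 99.999% of these values (99.9993% to 99.9996% per library) were whole multiples of the smallest in the cell, within a tolerance of 0.02. They are therefore log2(CPM + 1) by the authors, and whole UMI counts per cell were worked out from the step. The plan was written for count tables. As the unit was a log2 value, the planned count-based scaling tool was not used, and its planned substitute, the median of ratios, took its place.

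Depth was 14885765 and 12448164 UMIs in the CD45-negative and 24045901 and 36423571 UMIs in the CD45-positive libraries of 0 Gy and 4 Gy. Barcodes held 386 to 35226, 476 to 38102, 471 to 38362 and 307 to 37504 UMIs, in the same order. Median genes per barcode were 1192, 1301, 1410 and 1267. Cells with at least 200 genes and at most 20% mitochondrial counts were to be kept, which removed 0 barcodes (highest mitochondrial share 10.4% to 10.7%). Doublets were scored per library with Scrublet in scanpy, with exact neighbours and an expected rate of 0.8% per 1000 cells. Its automatic threshold marked 0.0669%, 0.203% and 0.0464% of barcodes in 3 libraries, under the planned limit of 0.5%, so that the highest scores up to the expected rate were removed there (286 barcodes in CD45-negative and 235 in CD45-positive at 0 Gy, and 149 in CD45-negative at 4 Gy). In the CD45-positive library of 4 Gy the automatic threshold removed 608 (6.33%). The cells kept numbered 5693 and 4164 CD45-negative and 5180 and 9000 CD45-positive, at 0 Gy and 4 Gy, 24037 in all.

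All libraries were clustered together: counts scaled to 10000 per cell and log-transformed, 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with random seed 0. All response lists and mitochondrial, ribosomal and haemoglobin genes were left out of the variable genes, so that the clusters were not built on the list members. Genes named outside the lists could be variable genes, and some of them lead the clusters in which they are compared. Epithelial and fibroblast clusters were clustered again on their own (1000 genes, 15 components, 10 neighbours), which gave 41 clusters. Clusters were named from 30 marker lists, 1 of them for cycling cells, by the markers among the 10 genes leading by fold over the upper quartile of the other clusters (genes in at least 20% of cells, 10 CPM added), with at least 3 detected markers. A cluster stayed unnamed where 3 or more markers of another lineage stood among its 25 leading genes, or where another class had as many leading markers by fold over the mean. The markers were fixed before the data were examined, while the second clustering and these details of naming were chosen after the data were examined. Names end in "-like" because they rest on markers alone.

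Classes with at least 50 cells in both libraries of a sort were compared, 3 in CD45-negative and 8 in CD45-positive cells, and the club-like class was described below that number because the series title names it. UMIs were summed per class and library and given as CPM of the class. Ratios carry an exact conditional binomial 95% interval, levels an exact Poisson one and shares of cells an exact (Clopper-Pearson) binomial one, all of counting error only. With 1 library per group no test was made. There were 16 response lists, fixed before the data were examined: p53 targets, type I interferon, interferon gamma, MHC class I, MHC class II, proliferation, inflammatory, immediate early and stress, club-secreted, antioxidant, alveolar transitional, extracellular matrix, T and NK effector, checkpoint, regulatory T and suppressive myeloid. A member was measured with at least 10 counts over both libraries, its log2 ratio used CPM + 5, and the median's interval came from 1000 Poisson redraws. The median was also ranked among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Folds against 0 counts were computed against a floor of 3 counts. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, with shallower cells left out.

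Genes were named by a rule fixed before the data were examined. For the club-like class and the 2 classes with the most cells in each sort, these were the 10 genes highest and the 10 lowest at 4 Gy by the bound of the ratio's interval nearest 1, among genes with at least 100 CPM in either library. For the other classes compared it was 3 each way. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T-cell receptor genes and predicted genes were left out, as were genes under 10% of their level in the class where they were highest, in both libraries. Members of the response lists could also be named. Those given as examples were picked after their values were seen, as were Xist, Trp53, Cdkn2a and the epithelial genes given as background. Of the genes this rule named in B-like cells, 1 is not reported here.

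The comparison was tested on simulated Poisson counts drawn from the real means and depths with 200 genes changed. Each gene's summed count was drawn on its own, so the clumping of UMIs in single cells was left out. The coverage below therefore holds for Poisson counting error and does not test the intervals on clumped counts. In endothelial-like cells (15794 genes) the 95% interval covered the true ratio in 38 of 40 genes set 0.25-fold, 42 of 45 at 0.5-fold, 44 of 45 at 1.5-fold, 23 of 23 at 2-fold and 41 of 42 at 4-fold, and in 96.1% of unchanged genes. In tumour-epithelial-like cells (8525 genes) it did so in 37 of 41, 40 of 40, 46 of 46, 17 of 17 and 41 of 45 genes, and 96.7% of unchanged ones. In B-like cells (14527 genes) it did so in 37 of 39, 41 of 42, 43 of 45, 19 of 20 and 40 of 45 genes, and 95.8%. A p53 list set 2-fold higher gave a median log2 ratio of 0.93 (0.94 set) in endothelial-like, 0.86 (0.84) in tumour-epithelial-like and 0.82 (0.72) in B-like cells, the set value being damped by the pseudocount.

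Alternatives fixed before the data were examined were a cell filter of 500 genes and 10% mitochondrial counts, every barcode kept, doublets kept, resolutions 0.5 and 2, random seed 1, response lists left in the variable genes, cells thinned to 1000 UMIs, the mean over cells of each cell's CPM, CPM without the 20 most abundant genes, the median of ratios, a pseudocount of 50 CPM and a minimum of 50 counts. Alternatives chosen after the data were seen were single clusters of endothelial-like, T-like, neutrophil-like and B-like cells on their own for the lists, the T-like ones also for the genes, the unnamed cluster added to the neutrophil-like class, club-like cells without the cell with the most Scgb1a1 UMIs, and tumour-epithelial-like cells without the cell with the most Spp1 UMIs. Gene coordinates come from GENCODE vM21 on GRCm38 (mm10), counted from 1. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.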

Results

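Single-cell RNA sequencing was carried out on mouse lungs carrying HKP1 tumours. HKP1 is a mouse lung adenocarcinoma line that lacks Trp53, the gene for the tumour suppressor p53, and it grows in the lung after injection into the tail vein. Female C57BL/6 mice of 8 weeks received 150000 HKP1 cells, were grouped by bioluminescence on day 6, and had either mock treatment (0 Gy) or 4 Gy of focal lung irradiation on each of 3 days in a row, day 10 to day 12. Lungs of 4 mice per treatment were taken 24 to 48 h after the last dose, and live cells were sorted into CD45-negative cells (epithelium, endothelium, stroma and tumour) and CD45-positive cells (leukocytes) before 10x Genomics 3′ libraries were made. The series title names the secretome of Scgb1a1-expressing club cells after radiation, so the comparison is 4 Gy against 0 Gy within each sort, with club cells of special interest. There were 4 libraries, 1 per dose and sort. The CD45-negative libraries held 5979 barcodes and 14885765 unique molecular identifiers (UMIs) at 0 Gy, and 4313 barcodes and 12448164 UMIs at 4 Gy. The CD45-positive libraries held 5415 barcodes and 24045901 UMIs at 0 Gy, and 9608 barcodes and 36423571 UMIs at 4 Gy. Median UMIs per barcode were 1894 and 2087 in the CD45-negative and 3096 and 2606 in the CD45-positive libraries, at 0 Gy and 4 Gy.

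With 1 library per group there was no replicate and no test. Each comparison gives the value at 0 Gy against the value at 4 Gy, as the CPM of the class (its UMIs scaled to a common total), and their ratio with an exact 95% interval in brackets. The intervals cover counting error only and say nothing of the spread between mice. Lists of genes are given by the median log2 ratio over their measured members. Over all measured genes the median log2 ratio lay within 0.06 of 0 in each of the 11 classes compared.

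Ptprc, which encodes CD45 (GRCm38 chromosome 1, 138062861 to 138175708, minus strand), followed the sort. It stood at 12.9 and 8.99 CPM in the CD45-negative libraries of 0 Gy and 4 Gy, and at 859.5 and 916 CPM in the CD45-positive ones. After each cell was thinned to 1000 UMIs, 0.409% and 0.204% of CD45-negative cells and 54.5% and 58.0% of CD45-positive cells had a Ptprc UMI (unthinned 0.966%, 0.624%, 86.2% and 84.5%). The thinning left out 564, 250, 209 and 426 cells as too shallow, in the same order.

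Endothelial-like cells made up most of the CD45-negative libraries, and lymphocytes most of the CD45-positive ones. Among leukocytes, neutrophil-like and interstitial-macrophage-like cells took a larger share at 4 Gy, and B-like cells, conventional-dendritic-cell-2-like (cDC2-like) cells and nonclassical-monocyte-like cells, the patrolling monocytes of the vessel wall, a smaller one. Neutrophil-like cells were 6.97% against 11.4%, ratio 1.63 [1.45 to 1.85], and interstitial-macrophage-like cells 2.72% against 4.03%, ratio 1.48 [1.22 to 1.81]. NK-like cells stood at 8.24% against 9.84%, ratio 1.19 [1.06 to 1.34], and T-like cells at 23.8% against 26.0%, ratio 1.09 [1.02 to 1.17]. B-like cells stood at 42.3% against 36.4%, ratio 0.860 [0.815 to 0.909], nonclassical-monocyte-like cells at 4.29% against 2.97%, ratio 0.692 [0.577 to 0.831], and cDC2-like cells at 3.20% against 1.92%, ratio 0.600 [0.482 to 0.747]. Classical-monocyte-like cells were 3.67% against 3.61%, ratio 0.985 [0.821 to 1.18]. In the CD45-negative libraries tumour-epithelial-like cells were 2.14% against 1.25%, ratio 0.583 [0.413 to 0.813], endothelial-like cells 83.5% against 85.7%, ratio 1.03 [0.983 to 1.07], and aerocyte-like cells, the large capillary cells of gas exchange, 7.73% against 7.20%, ratio 0.932 [0.802 to 1.08]. All shares were set by the sort, so that a larger share of 1 class leaves less for the others. Cells in clusters without a name made up 2.16% and 1.53% of the CD45-positive libraries and 0.580% and 0.456% of the CD45-negative ones. The largest such cluster carried neutrophil and monocyte markers (111 and 132 cells), and with it in the class the neutrophil-like ratio was 1.41.

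**Figure D1:**
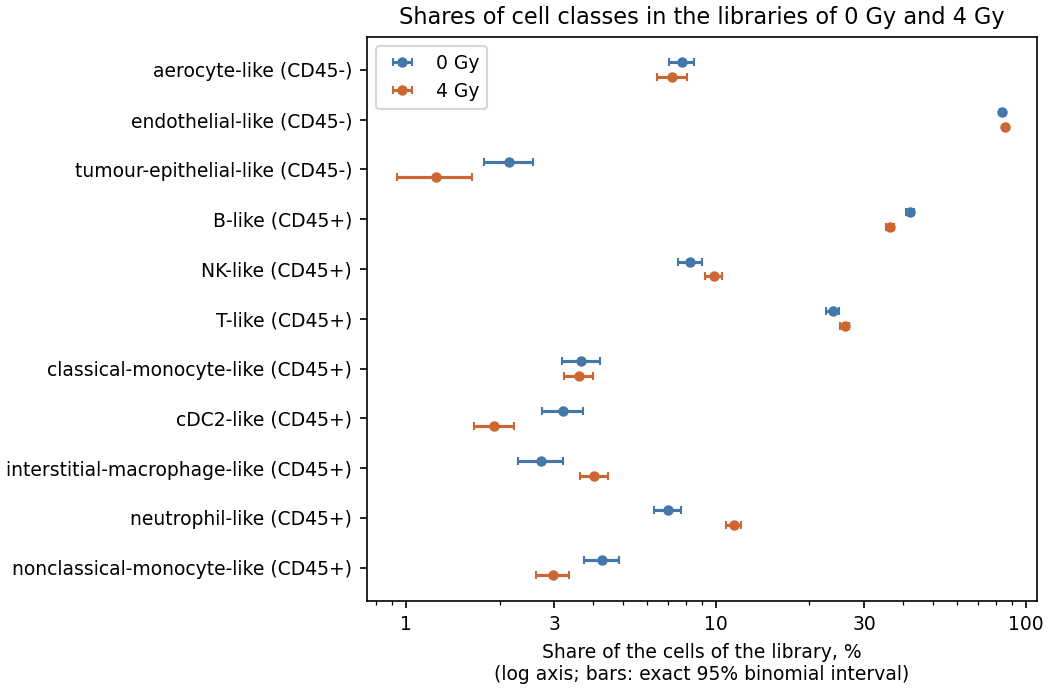
Share of cells of each compared class in its library (log axis, %), with exact 95% binomial intervals, in the 0 Gy and 4 Gy libraries of the same sort. Neutrophil-like cells stood at 6.97% in the 0 Gy and 11.4% in the 4 Gy library, and tumour-epithelial-like cells at 2.14% and 1.25%.

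In endothelial-like cells, targets of p53 were higher in the 4 Gy library as a group. Cdkn1a, which encodes the cell-cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), stood at 348 against 2306 CPM, ratio 6.63 [6.38 to 6.88]. Gdf15, a stress cytokine of the TGF-beta family (chromosome 8, 70629393 to 70632456, minus strand), stood at 7.12 against 227 CPM, ratio 32.0 [24.95 to 41.6]. Phlda3, a p53-induced inhibitor of Akt (chromosome 1, 135766119 to 135769136, plus strand), stood at 111 against 727 CPM, ratio 6.57 [6.14 to 7.03]. Of 23 measured members of the p53 list, 18 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 1.40 [1.33 to 1.53], at percentile 100 of random lists matched on expression. The list summed to 1846 against 6663 CPM. Eda2r, a receptor of the tumour necrosis factor family, stood at 0.657 against 41.6 CPM, ratio 63.3 [28.8 to 174], and the stress regulator Sesn2 at 2.96 against 63.7 CPM, ratio 21.5 [14.6 to 33.0]. The pro-apoptotic Bax stood at 223 against 884 CPM, ratio 3.96 [3.77 to 4.17], and Mdm2, the ligase that degrades p53, at 55.7 against 155 CPM, ratio 2.78 [2.50 to 3.08]. Trp53inp1 had a ratio of 5.96 [5.18 to 6.89] and Ccng1, cyclin G1, one of 5.63 [4.75 to 6.69], while Fas stood at 1.09 [1.03 to 1.16] and the repair gene Xpc at 1.19 [1.001 to 1.41]. Cluster 1 held 3960 of 4751 endothelial-like cells at 0 Gy and 878 of 3570 at 4 Gy. Cluster 3, led by Lyve1, held 125 at 0 Gy and 2288 at 4 Gy, so that these clusters largely followed the library. The 0 Gy cells of cluster 3 already had Cdkn1a at 1155 CPM, against 332 CPM in those of cluster 1. Within cluster 1 alone, an alternative chosen after the data were seen, the median was 0.75, and within cluster 3 alone 1.16.

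Outside that list, the 10 genes highest at 4 Gy in endothelial-like cells included a pair of circadian genes. Per3 (chromosome 4, 151003652 to 151044665, minus strand), a period gene, stood at 23.3 against 178 CPM, ratio 7.62 [6.59 to 8.84], and Tef (chromosome 15, 81802421 to 81826863, plus strand), a transcription factor under clock control, at 17.1 against 158 CPM, ratio 9.27 [7.84 to 11.0]. The labels give no time of day for either harvest. Dcxr, a carbonyl reductase, stood at 17.5 against 159 CPM, ratio 9.10 [7.72 to 10.8], Thyn1 at 21.0 against 110.1 CPM, ratio 5.24 [4.48 to 6.15], and the exocyst gene Exoc4 at 44.7 against 216 CPM, ratio 4.83 [4.33 to 5.39]. Among the 10 lowest were vascular genes. Mmp15, a membrane metalloproteinase, stood at 115 against 29.0 CPM, ratio 0.252 [0.218 to 0.291], and the apelin receptor gene Aplnr at 197 against 72.9 CPM, ratio 0.369 [0.336 to 0.405]. Gja4, which encodes a connexin of arterial endothelium, stood at 393 against 189 CPM, ratio 0.480 [0.452 to 0.510]. Hilpda, a lipid-droplet gene induced by hypoxia, had a ratio of 0.521 [0.506 to 0.536], the kinase gene Sgk1 0.527 [0.495 to 0.561] and the matrix gene Hmcn1 0.550 [0.527 to 0.573]. Hilpda and Hmcn1 were also among the leading genes of cluster 1. The others were Wfdc1 (0.458 [0.420 to 0.499]), Tspan8 (0.485 [0.452 to 0.522]), St6galnac3 (0.486 [0.432 to 0.545]) and Rnf144a (0.488 [0.461 to 0.517]).

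**Figure D2:**
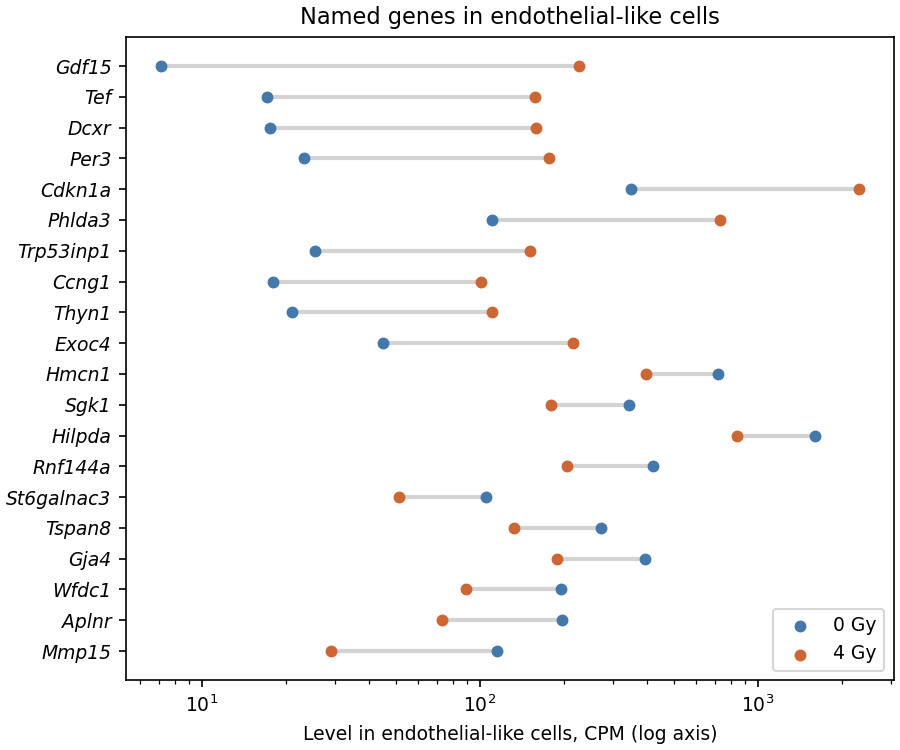
Level of the 20 named genes in endothelial-like cells (CPM, log axis), with 1 point for the 0 Gy and 1 for the 4 Gy library, joined by a line. Gdf15 moved from 7.12 to 227 CPM, and Mmp15 from 115 to 29.0 CPM.

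Further groups in endothelial-like cells moved less. Genes induced by type I interferon, the antiviral cytokines, were lower as a group, with a median log2 ratio of -0.26 [-0.38 to -0.20] and 0 of 22 higher and 5 lower by at least 1.5-fold. Isg15 stood at 159 against 104 CPM, ratio 0.655 [0.602 to 0.714], and Rsad2 at 22.99 against 12.2 CPM, ratio 0.533 [0.416 to 0.679]. Genes induced by interferon gamma had a median of -0.18 [-0.24 to -0.12], with the chemokine Cxcl10 higher (3.50 against 13.7 CPM, ratio 3.91 [2.62 to 5.99]) and the guanylate-binding protein gene Gbp4 lower (223 against 129 CPM, ratio 0.581 [0.539 to 0.626]). The major histocompatibility complex (MHC) class I list had a median of -0.14 [-0.16 to -0.11], and the class II list, which presents antigen to CD4 T cells, -0.20 [-0.26 to -0.17]. Immediate early and stress genes were higher (0.43 [0.38 to 0.52], 5 of 18 higher and 0 lower by at least 1.5-fold), with Egr1 at 11.8 against 31.8 CPM, ratio 2.69 [2.14 to 3.39] and Junb at 96.1 against 180.2 CPM, ratio 1.87 [1.72 to 2.04]. Matrix genes had a median of 0.29 [0.14 to 0.40] with 5 of 15 higher and 0 lower by at least 1.5-fold. The matricellular genes Ccn1 and Ccn2 stood at 13.7 against 83.4 CPM, ratio 6.10 [5.03 to 7.44] and at 24.0 against 79.1 CPM, ratio 3.30 [2.83 to 3.86], and elastin, Eln, at 66.9 against 122 CPM, ratio 1.82 [1.65 to 2.02]. The inflammatory list had a median of 0.19 [0.08 to 0.27], with the adhesion molecule gene Icam1 at 27.7 against 57.7 CPM, ratio 2.08 [1.79 to 2.44].

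Since cluster 1 held most of these cells at 0 Gy and cluster 3 most at 4 Gy, the medians were also computed within the endothelial clusters 1, 3, 12, 19 and 20, a choice made after the data were seen, and are given here in that order. For type I interferon genes they were -0.26, -0.18, -0.36, -0.64 and 0.18, with intervals that included 0 in cluster 3 ([-0.32 to 0.10]) and cluster 20 ([-0.15 to 0.42]). For interferon gamma genes they were 0.11, 0.00099, -0.27, -0.44 and -0.080, for MHC class I genes -0.047, 0.0081, -0.40, -0.10 and 0.046, and for MHC class II genes 0.078, 0.28, -0.016, -0.34 and 0.094. The negative medians of these lists over the whole class were thus found in some clusters and not in others. For immediate early genes the medians were 0.20, 0.28, 0.40, 0.78 and 0.36, and for matrix genes 0.084, 0.49, 0.17, 0.51 and 0.39. For the inflammatory list they were 0.043, 0.31, -0.64, 0.42 and 0.51, with intervals that included 0 in the first 3 of these clusters.

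The remaining lists in endothelial-like cells gave medians of 0.12 [0.05 to 0.20] for antioxidant genes, and 0.09 [-0.10 to 0.19] for the keratin and stress genes of transitional alveolar epithelium. They were 0.01 [-0.08 to 0.12] for club-secreted genes, 0.07 [-0.07 to 0.17] for checkpoint genes and -0.10 [-0.29 to 0.09] for regulatory T-cell genes. The suppressive myeloid list had a median of -0.14 [-0.24 to -0.03]. Its neutrophil gene S100a8 stood at 13.8 against 0.485 CPM, ratio 0.0352 [0.00944 to 0.0923], and the ratio was 0.0885 to 0.152 under 4 alternatives. No member of the T and NK effector list reached 10 counts there.

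Aerocyte-like cells, all in cluster 11, showed the p53 targets higher as well, with a median log2 ratio of 1.45 [1.35 to 1.68] and 18 of 22 higher and 0 lower by at least 1.5-fold. The list summed to 2986 against 10396 CPM. Gdf15 stood at 24.98 against 954 CPM, ratio 38.2 [27.4 to 54.8], Cdkn1a at 1097 against 4542 CPM, ratio 4.14 [3.91 to 4.38], Phlda3 at 545 against 1679 CPM, ratio 3.08 [2.84 to 3.35] and Bax at 275 against 952 CPM, ratio 3.46 [3.09 to 3.90]. Inka2, an inhibitor of the kinase Pak4, had 3 counts at 0 Gy and a ratio of 51.1 [17.1 to 251], or 20.2 in thinned cells. Ephx1 and Ces2e, both xenobiotic hydrolases, stood at 79.1 against 592 CPM, ratio 7.48 [6.13 to 9.21] and at 38.9 against 239.7 CPM, ratio 6.17 [4.61 to 8.38]. Dcxr had a ratio of 16.6 [8.98 to 33.9] (53.4 in thinned cells), Tef 7.68 [4.70 to 13.2], Trp53inp1 7.23 [5.03 to 10.7], Thyn1 5.47 [3.79 to 8.10] and Itpripl1 5.30 [3.74 to 7.68] (8.45 in thinned cells). Mdm2 had a ratio of 3.08 [2.34 to 4.10], which was 1.94 in thinned cells.

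Genes lower at 4 Gy in aerocyte-like cells included the water channel gene Aqp1, at 1523 against 886 CPM, ratio 0.582 [0.540 to 0.627], and the endothelial transcription factor gene Ets1, at 345 against 184 CPM, ratio 0.534 [0.453 to 0.629]. Hilpda had a ratio of 0.488 [0.438 to 0.544], and the aerocyte gene Car4, a carbonic anhydrase, one of 0.650 [0.623 to 0.678]. Car4 and Rprml (0.590 [0.509 to 0.683]) also lead cluster 11. The others were Mfap2 (0.522 [0.455 to 0.598]), AW112010 (0.589 [0.552 to 0.627]), Rtl8b (0.491 [0.380 to 0.630]), Abi3bp (0.566 [0.492 to 0.651]) and Abcc5 (0.541 [0.419 to 0.694]). Type I interferon genes had a median log2 ratio of -0.23 [-0.39 to 0.00], MHC class I genes -0.20 [-0.30 to -0.14], immediate early genes 0.49 [0.38 to 0.67] and matrix genes 0.58 [0.14 to 0.75]. The MHC class II list was higher (1.31 [0.95 to 1.59], 5 of 6 higher and 0 lower by at least 1.5-fold), at 88.1 against 269 CPM summed, against 3786 against 3160.3 CPM in endothelial-like cells. Its H2-Aa stood at 6.94 against 37.2 CPM, ratio 5.36 [2.65 to 12.0] and Cd74, the invariant chain, at 43.0 against 126 CPM, ratio 2.94 [2.17 to 4.02]. In thinned cells the list's median was 0.65 and with a pseudocount of 50 CPM 0.51; H2-Aa had a ratio of 2.89 in thinned cells and 2.03 with doublets kept, and Cd74 1.95 and 1.61.

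Tumour-epithelial-like cells numbered 122 at 0 Gy and 52 at 4 Gy, with the most in cluster E1 at both doses (55 and 26 cells). Cluster E8 held 28 and 12 of them, with a median of 19520 UMIs per cell over all libraries against 971 in E1. Summed levels of the class therefore weigh each E8 cell far more than each E1 cell. The class carried the epithelial keratin gene Krt19 at 2328 and 2669 CPM and Cdkn2a, the locus of p16 and Arf, at 703 and 354 CPM. Epcam, a further epithelial gene, was nearly absent, at 5 and 0 counts (6.71 and 0 CPM). It stood at 321 and 270 CPM in alveolar type II-like cells. The p53 list showed no common direction here, with a median log2 ratio of 0.04 [-0.22 to 0.39] and 3 of 17 higher and 2 lower by at least 1.5-fold. That median was 0.47 at resolution 0.5, 0.53 with doublets kept and 0.42 in thinned cells. Trp53 itself stood at 12.1 and 6.27 CPM, against 72.0 and 69.4 CPM in endothelial-like cells, and Xist, the RNA of the inactive X chromosome, at 8.05 and 3.14 CPM against 212 and 215 CPM. Cdkn1a was low at 12.1 against 65.9 CPM, ratio 5.45 [2.39 to 13.5]; its ratio was 1.48 as a mean over cells, 17.0 at clustering resolution 0.5 and 23.01 with doublets kept, and in thinned cells 2 counts were left at each dose. Genes of transitional alveolar epithelium were higher, with a median of 1.05 [0.59 to 1.22] and 6 of 9 higher and 1 lower by at least 1.5-fold. Keratin 8, Krt8, stood at 1221 against 1985 CPM, ratio 1.63 [1.47 to 1.80], and galectin 3, Lgals3, at 362 against 1057 CPM, ratio 2.92 [2.48 to 3.44]. Sprr1a stood at 22.8 against 166 CPM, ratio 7.29 [4.15 to 13.4], or 4.45 in thinned cells. As a mean over cells the list's median was 0.32. The keratin genes of the list are also among the markers by which this class was named. In alveolar type II-like cells, too few to compare, every measured member had a ratio below 1, from 0.132 for Tnip3 to 0.670 for Nupr1.

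Inflammatory genes in tumour-epithelial-like cells had a median of 0.94 [0.07 to 1.48] with 5 of 9 higher and 1 lower by at least 1.5-fold, and 0.32 at resolution 0.5 and 0.31 with a pseudocount of 50 CPM. The neutrophil-attracting chemokine genes Cxcl5 and Cxcl1 stood at 145 against 690.0 CPM, ratio 4.76 [3.77 to 6.05] and at 9.39 against 62.7 CPM, ratio 6.68 [2.71 to 18.7], and Cxcl3 had a ratio of 3.70 [2.31 to 5.99]. In thinned cells the ratios of Cxcl5 and Cxcl3 were 1.53 and 1.06, Cxcl1 had 2 counts at each dose, and the ratio of Cxcl3 was 2.18 as a mean over cells. Interferon gamma genes had a median of 0.39 [0.21 to 0.70], MHC class I genes 0.26 [0.13 to 0.45] and type I interferon genes -0.01 [-0.36 to 0.54], the last 0.63 in thinned cells and 0.66 with a minimum of 50 counts. Gbp2 had a ratio of 1.89 [1.47 to 2.44], and one of 0.774 in thinned cells and 0.969 as a mean over cells. Among the 3 genes highest at 4 Gy, Spp1, the secreted phosphoprotein osteopontin, stood at 335 against 2531 CPM, ratio 7.55 [6.54 to 8.73], with 86.6% of its 4 Gy counts in 1 cell and ratios of 4.16 to 4.91 under 4 alternatives, and 1.41 without the top cell of each library. Prl2c3 (40.2% in 1 cell) stood at 34.9 against 383 CPM, ratio 11.0 [7.14 to 17.5] and at ratios of 2.26 as a mean over cells and 2.18 in thinned cells. Fbln2, fibulin 2, stood at 9.39 against 122 CPM, ratio 13.02 [5.76 to 34.5], with 5.58 as a mean over cells and 7.77 with doublets kept. Cst9 was at least 13.4-fold lower (94 against 0 counts), Tm4sf20 had a ratio of 0.0205 [0.000515 to 0.117] on 1 count at 4 Gy, and S100g 0.0599 [0.0161 to 0.157]. In thinned cells Cst9 and Tm4sf20 had 5 counts each at 0 Gy and 0 at 4 Gy, too few for a fold, and S100g a ratio of at most 0.636. As means over cells the ratio of Cst9 was at most 0.141, and those of Tm4sf20 and S100g were 0.00875 and 0.154. Sftpc, the surfactant gene of alveolar type II cells, stood at 2312 against 28.2 CPM in the same class, with 1708 of its 1723 UMIs at 0 Gy in 1 cell.

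Among the classes compared, the p53 list stood apart in the endothelial-like and aerocyte-like cells. In leukocytes its median log2 ratio was 0.19 [0.09 to 0.25] in B-like, 0.10 [0.03 to 0.20] in T-like, 0.20 [0.10 to 0.43] in NK-like, 0.19 [0.02 to 0.35] in neutrophil-like and 0.20 [0.08 to 0.32] in interstitial-macrophage-like cells. Within neutrophil clusters 8 and 14 it was 0.33 and -0.0078. It was 0.03 [-0.05 to 0.26] in classical-monocyte-like, 0.02 [-0.08 to 0.31] in cDC2-like and -0.29 [-0.58 to -0.09] in nonclassical-monocyte-like cells. The last median lay much nearer to no change at resolution 0.5 and in thinned cells. Cdkn1a had ratios of 4.03 [2.53 to 6.73] in T-like cells, 3.76 [2.20 to 6.85] in NK-like cells, 3.89 [3.27 to 4.64] in cDC2-like cells and 1.92 [1.39 to 2.69] in classical-monocyte-like cells. The T-like ratio was 12.9 in thinned cells, and the cDC2-like one 2.23 in thinned cells and 6.06 at resolution 2. In interstitial-macrophage-like cells the ratio was 1.75 [1.58 to 1.94], in neutrophil-like cells 1.41 [1.28 to 1.55] and in B-like cells 1.74 [1.004 to 3.10], the last 1.001 in thinned cells. In nonclassical-monocyte-like cells it was 0.732 [0.466 to 1.14], with 1.57 at resolution 0.5, 1.23 with the response lists left in the clustering and 1.14 in thinned cells. The smaller CD45-negative classes were left out of this comparison. Of these, ciliated-like and club-like cells also had positive p53 medians, given below, the club-like one with an interval that included 0. Cdkn1a ratios were above 1 in alveolar type II-like, fibroblast-like and pericyte- and smooth-muscle-like cells too, so the higher level was not particular to endothelium.

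**Figure D3:**
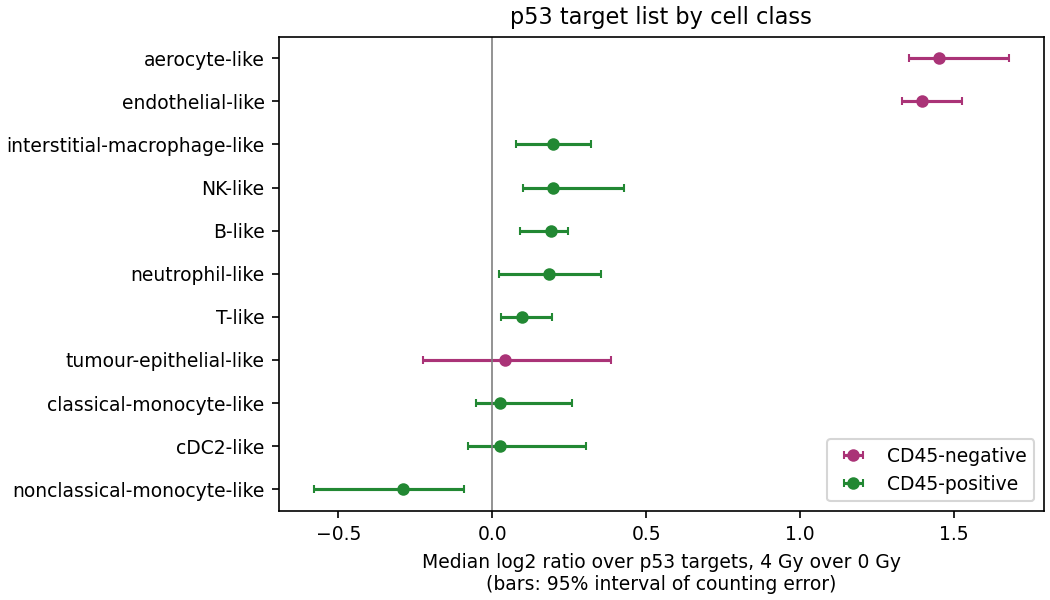
Median log2 ratio of the p53 target list, 4 Gy over 0 Gy, in 11 cell classes coloured by sort, with 95% intervals of counting error. Aerocyte-like (1.45) and endothelial-like cells (1.40) lie above 1.3, and the other 9 classes lie between -0.29 and 0.20.

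Club-like cells, the secretory cells of the bronchioles, were too few for a firm comparison, with 18 cells at 0 Gy and 20 at 4 Gy, 0.316% against 0.480%, ratio 1.52 [0.763 to 3.05] of the CD45-negative libraries. The ratio of shares was 0.937 under the stricter cell filter. The name rests on the cluster (E3) as a whole and does not show that each cell is a club cell. Of 20 club markers, 7 of the 18 cells at 0 Gy carried none and 4 carried 3 or more, against 5 and 8 of the 20 cells at 4 Gy. Scgb1a1, the club cell secretoglobin (chromosome 19, 9083636 to 9087958, minus strand), stood at 152705 against 60502 CPM, ratio 0.396 [0.381 to 0.412]. A single cell held 8461 of the 8462 Scgb1a1 UMIs at 0 Gy, and a single cell 51.7% of them at 4 Gy. The direction turned with the weight of those cells: the ratio was 1.76 as a mean over cells, 1.12 in thinned cells, and 1075 [193 to 42499] without the top cell of each library, a fold that rests on 1 count at 0 Gy against 1771. A Scgb1a1 UMI was seen in 2 of 18 and 7 of 20 cells before thinning, at median depths of 776 and 1602.5 UMIs, and in 1 of 8 and 3 of 12 thinned cells. The club-secreted list had a median log2 ratio of -3.13 [-3.89 to -2.13] with 3 of 21 higher and 14 lower by at least 1.5-fold, which was 0.18 in thinned cells and -0.20 without the top cells. Scgb3a2, a further secretoglobin gene, stood at 10719 against 15596 CPM, ratio 1.45 [1.31 to 1.61], or 3.45 and 6.76 under 2 alternatives, and Cyp2f2, a club cell cytochrome, at 2129 against 1353 CPM, ratio 0.636 [0.473 to 0.850], or 0.962 under 1. The p53 list had a median of 0.99 [-0.13 to 1.55] over 7 measured members, with Cdkn1a at 2 against 21 counts (9.60 [2.35 to 84.5]; 3.90 as a mean over cells and 20.2 with the response lists left in).

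Most of the genes named by size in club-like cells had the larger part of their counts in 1 cell. Lower at 4 Gy were the airway mucosal genes Scgb3a1 (1594 against 2 counts, 0.00115 [0.000139 to 0.00415]), Bpifb1 (0.00963 [0.000241 to 0.0549]) and Bpifa1 (at least 55.0-fold), with 100% of the 0 Gy counts of each in 1 cell. Muc5b (at least 16.8-fold), Tff2 (at least 14.9-fold), Reg3g (at least 12.4-fold) and Ltf (at least 12.0-fold) came from 1 cell too. Ccl20 (at least 5.83-fold), Lypd2 (0.110 [0.0425 to 0.242]) and Pglyrp1 (0.0457 [0.00110 to 0.286]) were spread over 2 to 5 cells at 0 Gy, with 87.5%, 65.5% and 45% of the counts in 1 cell. Higher at 4 Gy were genes of heart muscle with 0 counts at 0 Gy, Myl7 (at least 38.1-fold), Myl4 (at least 32.9-fold), Tcap, Tnni3, Tnnt2, Sln, Actc1 and Myoz2 (at least 7.01-fold), with 69.2% to 93.5% of the counts of each in 1 cell. Cytl1 came wholly from 1 cell (at least 5.49-fold), and the long noncoding RNA Neat1 had a ratio of 7.82 [3.91 to 17.8], with 45.5% of the counts in 1 cell. Except for Myoz2, the ratio of each of these 20 genes moved by more than 1.5 times under at least 1 alternative. None turned direction under the alternatives that gave a fold. Removal of the top cell was not run for these genes, so a kept direction says little where 1 cell held most of the counts.

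Outside club-like and ciliated-like cells, more cells carried Scgb1a1 at 4 Gy. In thinned cells of all other classes 0.921% of CD45-negative cells at 0 Gy and 5.53% at 4 Gy had a Scgb1a1 UMI, and 0.201% and 0.863% of CD45-positive cells did. Over all cells of each library, with those classes left in and without thinning, the shares were 2.44% and 13.1%, and 0.869% and 3.34%. In endothelial-like cells, which should lack the gene, Scgb1a1 stood at 9.96 against 76.3 CPM, ratio 7.66 [6.14 to 9.65], at median depths of 1798 and 1974 UMIs, with 124 of the 629 UMIs at 4 Gy in 1 cell. Aerocyte-like cells had 9.02 against 45.0 CPM, ratio 4.99 [2.68 to 9.99] (3.23 with doublets kept), and T-like cells 1.12 against 8.49 CPM. In aerocyte-like cells 8 of the 13 UMIs at 0 Gy lay in 1 cell. Cells above 20000 CPM of Scgb1a1 numbered 1 at 0 Gy and 9 at 4 Gy in the CD45-negative libraries. Of these 9, 4 were club-like, 3 ciliated-like and 2 of other classes, and 4 cells lay within a factor of 2 of that limit. The alveolar type II gene Sftpc was lower in the same endothelial-like cells, at a ratio of 0.626 [0.513 to 0.763].

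**Figure D4:**
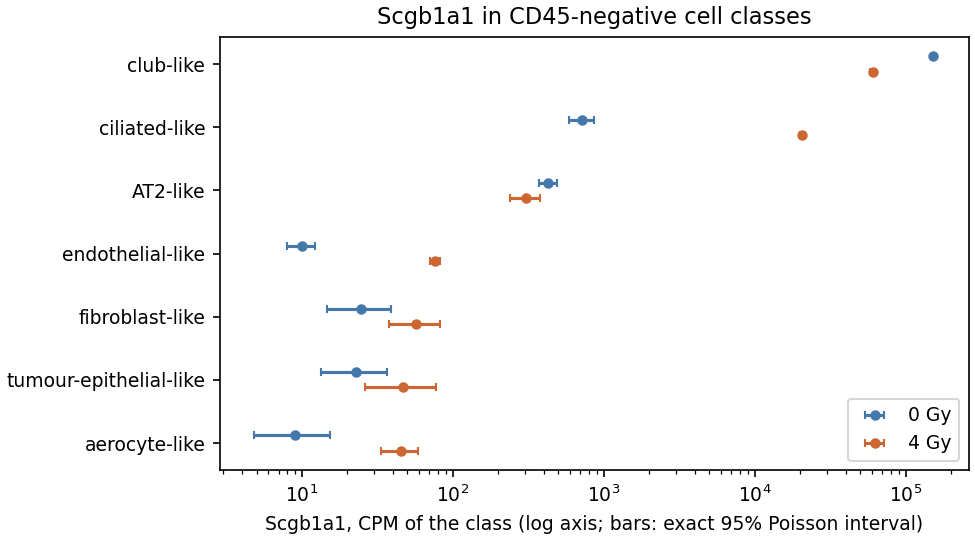
Scgb1a1 level in CD45-negative classes (CPM of the class, log axis), with exact 95% Poisson intervals, in the 0 Gy and 4 Gy libraries. Endothelial-like cells stand at 9.96 and 76.3 CPM, and the club-like value of 152705 CPM at 0 Gy rests on 1 cell.

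Among lymphocytes, B-like cells had 1719 of 2191 cells at 0 Gy and 2631 of 3275 at 4 Gy in cluster 2. Interferon-induced genes were lower in them, with a median log2 ratio of -0.22 [-0.29 to -0.12] over the type I list and Ifi27l2a at 659 against 404 CPM, ratio 0.613 [0.587 to 0.640] and Ifi214 at 0.642 [0.575 to 0.717]. Pax5, the B-lineage transcription factor, stood at 261 against 355 CPM, ratio 1.36 [1.29 to 1.44], the cyclin gene Ccnd3 at a ratio of 1.41 [1.28 to 1.55], Wdfy4 at 1.48 [1.34 to 1.63] and Hipk1 at 1.42 [1.28 to 1.57]. Jchain, the joining chain of secreted antibodies, stood at 79.4 against 363 CPM, ratio 4.57 [4.18 to 5.01], with 23.1% of the counts in 1 cell. Its ratio was 2.94 in thinned cells and 2.79 as a mean over cells, and turned to 0.586 under the stricter cell filter and 0.387 with the response lists left in. The splicing gene Snrpd2 (1.46 [1.32 to 1.62]) was higher, and Srsf2 (0.683 [0.630 to 0.741]), Ost4 (0.669 [0.604 to 0.742]) and the respiratory gene Cox6c2 (0.720 [0.654 to 0.792]) were lower. Of the other named genes, Olfr77 (2.65) and Tpt1-ps3 (1.33) were higher, and H3f3a (0.670), Myl12b (0.660), Tpt1 (0.731), Ptma (0.730) and Ndufb1-ps (0.701) lower. These have pseudogenes or close relatives among the genes listed, so that their counts are uncertain. The gene model CT010467.1 had a ratio of 1.41.

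In T-like cells, the chemokine receptor gene Cxcr6 stood at 276 against 150.2 CPM, ratio 0.545 [0.505 to 0.588], and Cxcr3 at 153 against 88.8 CPM, ratio 0.579 [0.524 to 0.641]. S100a4 stood at 352 against 160.3 CPM, ratio 0.456 [0.424 to 0.489]. Also among the 10 lowest were S100a6 (0.673 [0.646 to 0.701]), S100a11 (0.695 [0.653 to 0.740]), Hopx (0.608 [0.550 to 0.672]) and Ccl4 (0.650 [0.609 to 0.695]), the last with 38.6% of counts in 1 cell. Among the 10 highest, Satb1, a chromatin organiser of T cells, stood at 361 against 489.7 CPM, ratio 1.36 [1.29 to 1.43], and the survival gene Bcl2 at 451 against 624 CPM, ratio 1.38 [1.32 to 1.45]. Igfbp4 stood at 188 against 279 CPM, ratio 1.49 [1.38 to 1.60], and Rflnb at a ratio of 1.61 [1.43 to 1.82]. Granzyme B, Gzmb, a cytotoxic effector, stood at 47.3 against 100.2 CPM, ratio 2.12 [1.84 to 2.45]. The T and NK effector list had a median of -0.20 [-0.26 to -0.12] with 1 of 12 higher and 0 lower by at least 1.5-fold, and Ccl5 had a ratio of 0.856 [0.840 to 0.872]. Checkpoint genes had a median of -0.02 [-0.18 to 0.08], with Pdcd1, the gene of PD-1, at 90.5 against 58.9 CPM, ratio 0.651 [0.573 to 0.740]. Regulatory T-cell genes had a median of 0.04 [-0.09 to 0.16] with Foxp3 at 0.951 [0.763 to 1.19], and type I interferon genes -0.24 [-0.29 to -0.11]. Cluster 6 held the most T-like cells at 0 Gy (350 of 1232) and cluster 7 at 4 Gy (665 of 2339). The mix differed, with cluster 10 at 6.68% against 5.08% of cells of the library, ratio 0.760 [0.660 to 0.877], cluster 7 at a ratio of 1.38 [1.20 to 1.60] and cluster 9 at 1.33 [1.15 to 1.55]. Within clusters 6, 7, 9 and 10, in that order, the effector median was -0.050, 0.077, 0.32 and -0.036, so that the lower median of the whole class was not found in any of them at that size. The type I interferon median was 0.020, -0.49, -0.14 and -0.13, and the proliferation median -0.32, -0.49, 0.11 and -0.32. The genes were also taken within these clusters, a choice made after the data were seen. In clusters 6 and 10 Cxcr6 stood at ratios of 0.675 [0.602 to 0.758] and 0.597 [0.533 to 0.667], Cxcr3 at 0.707 [0.614 to 0.815] and 0.684 [0.587 to 0.796], and S100a4 at 0.447 [0.397 to 0.502] and 0.682 [0.623 to 0.746]. Cxcr6 is among the genes leading cluster 10, and the differences of Cxcr6 and Cxcr3 were smaller there and in cluster 6 than over the whole class. In cluster 9 Cxcr6 had a ratio of 1.21 [0.881 to 1.69]. Ccl4 went opposite ways, at 0.394 [0.362 to 0.428] in cluster 6 and 3.89 [3.34 to 4.54] in cluster 10, and Gzmb stood at 1.47 [1.21 to 1.79] and 4.86 [3.88 to 6.14]. S100a6 was at 0.813 and 0.820 in these clusters, and 2.10 [1.35 to 3.36] in cluster 9. The other named genes were Gmfg (1.46), Eif3m (1.46) and Snrpg (1.52), higher, and Snrpf (0.627), lower, with Olfr77 (2.54), Tpt1-ps3 (1.40), Myl12b (0.654) and Hist1h2ap (0.678) uncertain because of copies.

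NK-like cells (cluster 4) carried more Il18rap, a subunit of the interleukin 18 receptor, at 281 against 481 CPM, ratio 1.71 [1.52 to 1.93], and more Adamts14 (1.85 [1.46 to 2.36]) and Olfr77 (2.62). Less abundant were Xcl1, the chemokine that draws cross-presenting dendritic cells (591 against 357 CPM, ratio 0.605 [0.547 to 0.669]), Emb (0.565 [0.460 to 0.694]) and Ptma (0.647). The effector list had a median of 0.07 [0.05 to 0.12] with 0 of 12 higher and 1 lower by at least 1.5-fold.

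In interstitial-macrophage-like cells (cluster 13) Ccl24, the eosinophil chemokine eotaxin 2, stood at 44.6 against 649 CPM, ratio 14.6 [11.5 to 18.7], or 8.30 as a mean over cells. Arginase 1, Arg1, stood at 264 against 1035 CPM, ratio 3.92 [3.55 to 4.35], or 8.41 in thinned cells, and Spp1 at 565 against 1516 CPM, ratio 2.68 [2.50 to 2.88]. These 3 genes also lead cluster 13. The suppressive myeloid list had a median log2 ratio of 0.43 [0.31 to 0.52] with 6 of 15 higher and 0 lower by at least 1.5-fold. Its Nos2 had 1 count at 0 Gy and a ratio of 38.1 [6.67 to 1521], or at least 1.18 in thinned cells. Matrix genes had a median of 1.38 [1.12 to 1.60] over 4 measured members, or 0.76 with a pseudocount of 50 CPM. Fibronectin, Fn1, stood at 1050.2 against 1828 CPM, ratio 1.74 [1.65 to 1.84]. The protease inhibitor gene Timp1 stood at 5.74 against 50.7 CPM, ratio 8.83 [4.56 to 19.6] (2.49 in thinned cells), and Tgfb1 had a ratio of 1.06 [0.956 to 1.17]. Type I interferon genes were higher as a group, with a median of 0.57 [0.39 to 0.73] and 11 of 23 higher and 0 lower by at least 1.5-fold. Isg15 stood at 112 against 232 CPM, ratio 2.07 [1.76 to 2.45], and Ifit1 at 15.3 against 48.0 CPM, ratio 3.14 [2.05 to 5.03]. Irf7 had a ratio of 2.10 [1.60 to 2.80] and Rsad2 one of 3.03 [1.93 to 4.97]. In thinned cells the ratios of Ifit1, Irf7 and Rsad2 were 5.51, 5.71 and at least 1.71. The fractalkine receptor gene Cx3cr1 (119.8 against 57.8 CPM, ratio 0.482 [0.395 to 0.589]), Tmem176a (0.506 [0.447 to 0.572]) and Tmem176b (0.555 [0.501 to 0.616]) were lower. Jchain had 98.1% of its counts in 1 cell (4.26 [3.30 to 5.58]; 1.97 to 6.42 under 3 alternatives).

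Neutrophil-like cells lay mainly in cluster 8 (199 of 361 cells at 0 Gy and 663 of 1024 at 4 Gy). Inflammatory genes were lower in them, with a median of -0.49 [-0.55 to -0.37] and 1 of 17 higher and 8 lower by at least 1.5-fold. Prostaglandin synthase 2, Ptgs2, stood at 1393 against 822 CPM, ratio 0.590 [0.553 to 0.629], and interleukin 1 alpha, Il1a, at 241 against 114 CPM, ratio 0.472 [0.401 to 0.557]. Il1b had a ratio of 0.840 [0.822 to 0.859], and the monocyte chemokine Ccl2 one of 0.185 [0.1204 to 0.278], or 0.342 to 0.450 under 5 of the alternatives. Immediate early genes had a median of -0.39 [-0.44 to -0.32], and Nr4a1, an immediate early nuclear receptor, stood at 419.6 against 179 CPM, ratio 0.426 [0.375 to 0.483]. Wfdc17, a gene of activated myeloid cells, was higher at 1046 against 2684 CPM, ratio 2.57 [2.42 to 2.73], as was Ifitm6 (109.7 against 294 CPM, ratio 2.68 [2.22 to 3.26]), at 1.37 to 1.73 under 4 alternatives. The suppressive list had a median of 0.20 [0.00 to 0.28] with S100a8 at 1.28 [1.27 to 1.30], and type I interferon genes one of 0.30 [0.19 to 0.44]. Within clusters 8 and 14 the type I interferon medians lay on opposite sides of 0, at 0.59 [0.42 to 0.71] and -0.55 [-0.79 to -0.38]. The inflammatory medians there were -0.30 and -1.15, the immediate early ones -0.32 and -0.60, and the suppressive ones 0.14 and -0.19. The B-cell markers Cd79b (489 against 232 CPM, ratio 0.474 [0.423 to 0.532]) and Ebf1 (323 against 156 CPM, ratio 0.482 [0.418 to 0.555]) were lower in the same class. Jchain had 97.7% of its counts in 1 cell (59.0 [25.2 to 182]), and its ratio was 12.9 in thinned cells, 5.10 as a mean over cells and 0.231 at resolution 2.

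The MHC class II list had negative medians in both monocyte classes. Classical-monocyte-like cells (cluster 15) had one of -0.51 [-0.58 to -0.42] with 0 of 7 higher and 1 lower by at least 1.5-fold, with Cd74 at 5907 against 3868 CPM, ratio 0.655 [0.633 to 0.677] and H2-Aa at 0.675 [0.632 to 0.720]. The intervals of H2-DMa (0.911 [0.806 to 1.03]), H2-DMb1 (0.861 [0.738 to 1.01]) and Ciita (0.790 [0.624 to 1.002]) included 1. Nonclassical-monocyte-like cells (cluster 16) had one of -0.56 [-0.70 to -0.42] with 0 of 7 higher and 3 lower by at least 1.5-fold, with H2-Eb1 at 691 against 366 CPM, ratio 0.529 [0.442 to 0.632] and Cd74 at 0.711 [0.664 to 0.761]. The intervals of H2-DMa (1.30 [0.810 to 2.10]), H2-DMb1 (0.594 to 1.69) and Ciita (0.499 [0.232 to 1.03]) included 1 there. Type I interferon genes had medians of -0.19 [-0.28 to -0.07] and -0.37 [-0.61 to -0.13] in these classes and -0.07 [-0.25 to 0.04] in cDC2-like cells. In classical-monocyte-like cells versican, Vcan, stood at 55.6 against 168 CPM, ratio 3.03 [2.31 to 4.01], and Olfr77 at a ratio of 2.39 (1.46 in thinned cells). Cxcl10 had 49.2% of its counts in 1 cell and a ratio of 3.53 [2.46 to 5.19], or 2.19 as a mean over cells and 6.69 with the response lists left in. Bcl2a1d (0.385 [0.308 to 0.481]) and the heat shock gene Hspa1b (0.298 [0.213 to 0.412]) were lower, as was the histone gene Hist1h2ap (0.192 [0.152 to 0.241]). Hist1h2ap had 72.9% of its counts in 1 cell, and its ratio was 0.343 as a mean over cells and 0.575 with the response lists left in. In nonclassical-monocyte-like cells apolipoprotein E, Apoe, stood at 4456 against 2595 CPM, ratio 0.582 [0.544 to 0.623]. The lipid-droplet gene Plin2 (0.526 [0.401 to 0.687]) and Lfng (0.455 [0.290 to 0.703], 0.938 in thinned cells) were also among the 3 lowest, and Dpep2 (2.15 [1.54 to 3.03]), Serpinb10 (2.09 [1.51 to 2.93]) and Tpt1-ps3 (1.75) were the 3 highest. The cDC2-like cells (cluster 17) had Ccl17, a chemokine for CCR4-bearing T cells that also leads that cluster, at 602 against 1409 CPM, ratio 2.34 [2.18 to 2.51] (1.33 in thinned cells), with Olfr77 at 2.39 (3.64 in thinned cells). Rtl8a (0.401 [0.300 to 0.530]) and transferrin, Trf (0.438 [0.344 to 0.555]), were lower there, as was Jchain, with 99.7% of its counts in 1 cell (0.00276 [0.000751 to 0.00708]; 0.00134 to 0.0552 under 4 alternatives, the last a bound on 0 counts).

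Proliferation genes, those of DNA replication and mitosis, summed lower at 4 Gy in several classes. Some sums rest mainly on abundant members and so need not follow the other genes of the list. At 0 Gy Stmn1 and Hmgb2 had 306 and 63 of the 476 counts in aerocyte-like cells. Hmgb2 had 210 of 388 in classical-monocyte-like cells. Endothelial-like cells had 729 against 532 CPM, ratio 0.730 [0.702 to 0.758], with a median log2 ratio of -0.31 [-0.41 to -0.22]; the mitotic genes Ube2c (9.41 against 0.970 CPM, ratio 0.103 [0.0431 to 0.212]), Cdk1 (0.142 [0.0437 to 0.361]) and Top2a (0.216 [0.0875 to 0.467]) were lowest. Within clusters 1, 3, 12, 19 and 20 that median was -0.27, -0.029, -0.49, 0.20 and -0.41. With the response lists left in the clustering it was 0.011, and the ratios of the 3 genes were 0.880, 0.688 and 1.10; as means over cells they were 0.234, 0.215 and 0.123. Sums were 915 against 689.9 CPM, ratio 0.754 [0.726 to 0.783] in T-like cells, and 558 against 329 CPM, ratio 0.589 [0.540 to 0.643] in interstitial-macrophage-like cells. They were 1058 against 782 CPM, ratio 0.739 [0.688 to 0.793] in cDC2-like cells and 327 against 211 CPM, ratio 0.647 [0.560 to 0.747] in classical-monocyte-like cells. The last ratio was 0.982 with the response lists left in, where the median of -0.78 turned to 0.036 (-0.05 in thinned cells and -0.17 with a pseudocount of 50 CPM), and the T-like median of -0.40 turned to 0.0043. The interstitial-macrophage-like median was -0.52 [-0.72 to -0.36], with 0 of 22 higher and 8 lower by at least 1.5-fold. Tumour-epithelial-like cells had the highest sums of the CD45-negative classes compared, 2222 against 1929 CPM, ratio 0.868 [0.790 to 0.953], with a median of -0.19 [-0.46 to 0.04] and 7 of 22 higher and 7 lower by at least 1.5-fold. Ratios were 0.817 [0.706 to 0.945] in aerocyte-like, 1.01 [0.956 to 1.06] in B-like, 0.969 [0.861 to 1.09] in neutrophil-like and 0.901 [0.709 to 1.15] in nonclassical-monocyte-like cells (1.61 in thinned cells). The NK-like ratio was 1.11 [1.01 to 1.22], with a median of 0.35 [0.11 to 0.57] and 7 of 21 higher and 0 lower by at least 1.5-fold. The median turned to -0.29 in thinned cells, and the ratio to 0.736 in thinned cells, 0.902 as a mean over cells and 0.830 with the response lists left in. The cDC2-like ratio was 1.05 in thinned cells. In club-like cells the sum was 41 against 9 counts, and its ratio of 0.201 turned to 1.09 under the stricter cell filter.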

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

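All tests and the rule behind this part were chosen after the values were seen. Results below are lists with classes of the same sort on opposite sides of 0 beyond counting error and with a median of at least 1.5-fold in either direction. All lists in the 11 classes compared were searched, and 5 lists met this. Of the rules tried before it, one over whole libraries gave none and one over the reported lists only gave 1. The MHC class II list had a median log2 ratio of 1.31 in aerocyte-like and -0.20 in endothelial-like cells. The list summed to 88.1 against 269 CPM in aerocyte-like cells and 3786 against 3160.3 CPM in endothelial-like cells, so that the aerocyte-like level stayed far below the endothelial-like one at both doses. The aerocyte-like median was 0.65 in cells thinned to 1000 UMIs and 0.51 with a pseudocount of 50 CPM. Within endothelial clusters 1, 3, 12, 19 and 20 the list's median was 0.078, 0.28, -0.016, -0.34 and 0.094, so that the opposite direction was not kept in clusters 1, 3 and 20.

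The suppressive myeloid list stood at 1.61 in tumour-epithelial-like cells, over 4 measured members, and -0.14 in endothelial-like cells. The former was 0.26 without the cell with the most Spp1 UMIs in each library. The latter turned to 0.17 in cluster 12 and 0.13 in cluster 19. The club-secreted list stood at 0.64 in aerocyte-like cells, over 2 measured members, and -0.17 in tumour-epithelial-like cells. The first of these turned to -0.63 with doublets kept, and the second to 0.12 under the stricter cell filter and 0.082 in thinned cells. The T and NK effector list stood at 0.35 in B-like cells and at -2.41 in nonclassical-monocyte-like cells, over 2 measured members, the latter 0.11 with doublets kept. The proliferation list stood at 0.35 in NK-like cells, which turned to -0.29 in thinned cells, and at -0.78 in classical-monocyte-like cells, which turned to 0.036 with the response lists left in. Outside the classes compared, the club-secreted list stood at -3.13 in club-like and 3.01 in ciliated-like cells, both classes of few cells. None of these differences between classes was tested, since each dose has 1 library.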

How the results depend on the processing

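The alternatives built on single clusters, on the unnamed cluster and on the top Scgb1a1 and Spp1 cells were chosen after the data were seen; the others were planned. No paired analysis was possible because each group has 1 library and the results come from no test. A direction is called where the counting interval excludes no change. Of 225 gene ratios 223 had such a direction, and 211 of these kept it under all alternatives (1993 values for genes). Of 77 list results 60 had one and 39 kept it (922 values), and of 12 class shares 8 had one and all 8 kept it (80 values). Genes named by size were ranked by the bound of this same interval, so that their having a direction was largely set by the choice. All alternatives reuse the same libraries, so a kept direction says nothing of the spread between mice. Removal of the top cell was run only for Scgb1a1 in club-like cells, Spp1 in tumour-epithelial-like cells and 1 list in each class. A kept direction of other genes with most counts in 1 cell was therefore not tested in that way. Of the results without a clear direction, 2 of 2 genes, 13 of 17 lists and 1 of 4 shares lay on the other side under at least 1 alternative. The share was that of club-like cells (0.937 under the stricter filter). Values that left the counting interval without a called direction turning numbered 287 for single genes and 8 for main gene results, 149 and 39 for lists, and 2 for shares. Classical-monocyte-like cells gave no value at resolution 0.5, and club-like cells none with doublets kept or at resolutions 0.5 and 2, since no such class was named there. A further 18 gene values were too low for a fold, with both counts at or under the floor of 3 or a bound that decides no direction. In thinned cells these were Cst9 and Tm4sf20 (5 against 0 counts each) and Cdkn1a and Cxcl1 (2 against 2) in tumour-epithelial-like cells. In thinned club-like cells they were Bpifb1 and Muc5b (3 against 0), Reg3g (2 against 0), Ltf and Tff2 (1 against 0), Neat1 (1 against 3), Cdkn1a (0 against 3) and Myoz2 (0 against 4), and under the stricter cell filter Myl4 (0 against 2) and Sftpc (1 against 1). In T-like cluster 7 they were Cxcr3 (1 against 1), Gzmb (0 against 3) and Pdcd1 (0 against 2), and in cluster 9 Pdcd1 (0 against 4). This limit was set after the data were seen. The cause was not tested for any value below, except where stated. Depth limits the genes measured, with 1685 in club-like, 8570 in nonclassical-monocyte-like and 8626 in tumour-epithelial-like cells and 15825 in endothelial-like cells.

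Called directions that turned come first. In thinned cells these were Scgb1a1 (1.12) and the club-secreted median (0.18) in club-like cells, and Gbp2 (0.774) and Krt19 (0.828) in tumour-epithelial-like cells. The summed proliferation ratio turned in thinned NK-like (0.736) and cDC2-like cells (1.05), and so did the proliferation median in NK-like (-0.29) and the club-secreted median in tumour-epithelial-like cells (0.082). As means over cells, Scgb1a1 (1.76) and Sftpc (0.941) turned in club-like cells, Gbp2 (0.969) and Krt19 (0.938) in tumour-epithelial-like cells, and summed proliferation in NK-like cells (0.902). The stricter cell filter turned Jchain in B-like cells (0.586), the club-secreted median in tumour-epithelial-like cells (0.12) and summed proliferation in club-like cells (1.09). Doublets kept turned the effector median in nonclassical-monocyte-like (0.11) and the club-secreted median in aerocyte-like cells (-0.63). Within single clusters, endothelial medians turned for MHC class II (0.078 in cluster 1, 0.28 in 3 and 0.094 in 20), interferon gamma (0.11 in 1 and 0.00099 in 3), MHC class I (0.0081 in 3 and 0.046 in 20), type I interferon (0.18 in 20), the inflammatory list (-0.64 in 12), the suppressive list (0.17 in 12 and 0.13 in 19) and proliferation (0.20 in 19). T-like medians turned for type I interferon in cluster 6 (0.020), effector genes in clusters 7 (0.077) and 9 (0.32) and proliferation in cluster 9 (0.11). T-like genes turned in cluster 7 for Ccl4 (5.13), Ccl5 (1.83) and S100a6 (1.54), in cluster 9 for Ccl4 (6.48), Ccl5 (1.79), Cxcr6 (1.21) and S100a6 (2.10) and in cluster 10 for Ccl4 (3.89) and Hist1h2ap (1.29), with 1 count of Ccl4 at 0 Gy in each of clusters 7 and 9. Neutrophil-like medians turned in cluster 14 for p53 targets (-0.0078) and type I interferon (-0.55). Resolution 2 turned Jchain in neutrophil-like cells (0.231). With the response lists left in, Jchain in B-like cells (0.387), Sftpc in club-like cells (0.711), Top2a in endothelial-like cells (1.10), summed proliferation in NK-like cells (0.830), and the proliferation medians in T-like (0.0043), classical-monocyte-like (0.036) and endothelial-like cells (0.011) turned. Without the top cell of each library, Scgb1a1 in club-like cells turned to 1075, on 1 count at 0 Gy.

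Main values that moved without a called direction turning are these. Scgb1a1 in club-like cells was 0.325 without the 20 most abundant genes, 0.328 by the median of ratios, 0.259 under the stricter filter and 0.313 with the response lists left in. The club-secreted median was -1.35 as a mean over cells, -0.91 with a minimum of 50 counts and -0.20 without the top cells. The p53 median was 0.21 in T-like cluster 6 alone, 0.75 in cluster 1 alone, 1.16 in cluster 3 alone, 0.73 in cluster 20 alone and 0.85 with a pseudocount of 50 CPM in endothelial-like cells, which damps low genes by construction. With that pseudocount it was 0.91 in aerocyte-like, 0.055 in B-like and 0.072 in interstitial-macrophage-like cells. In tumour-epithelial-like cells it was 0.47 at resolution 0.5, 0.42 in thinned cells and 0.53 with doublets kept, in nonclassical-monocyte-like cells -0.020 at resolution 0.5 and -0.030 in thinned cells, and in thinned cDC2-like cells 0.55. The CD45-positive over CD45-negative ratio of Ptprc was 111 and 250.0 in thinned cells and 85.9 and 177 as a mean over cells, at 0 Gy and 4 Gy. The neutrophil-like share ratio was 1.42 with doublets kept and 1.41 with the unnamed cluster added.

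Summed proliferation ratios moved in thinned cells to 1.10 in B-like, 0.900 in T-like, 0.831 in classical-monocyte-like, 0.478 in interstitial-macrophage-like, and 0.844 in neutrophil-like cells. As means over cells they were 0.815 in T-like, 0.870 in classical-monocyte-like, 0.831 in cDC2-like, 0.538 in interstitial-macrophage-like and 0.688 in tumour-epithelial-like cells. With the response lists left in they were 1.13 in B-like, 0.958 in T-like, 0.982 in classical-monocyte-like, 0.720 in club-like, 0.904 in cDC2-like, 0.799 in endothelial-like and 0.834 in interstitial-macrophage-like cells. Other moves were to 0.775 in tumour-epithelial-like cells at resolution 0.5, 0.647 in cDC2-like cells at resolution 2, and 1.28 in NK-like cells under the stricter filter. Without a clear direction at first, the ratio crossed 1 from 0.901 to 1.61 in thinned nonclassical-monocyte-like cells and from 1.01 to 0.874 in B-like cells with doublets kept.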

Other observations

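All tests of explanations in this part, the clock gene list, and the choice of the patterns weighed were made after the values were seen.

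Ciliated-like cells, the motile-cilia cells of the airway, numbered 20 at 0 Gy and 35 at 4 Gy and were left out of the comparisons for that reason. Their share was 0.351% against 0.841%, ratio 2.39 [1.34 to 4.37]. Scgb1a1 stood at 716 against 20437 CPM, ratio 28.6 [23.7 to 34.6] in them, and Scgb3a2 at 12.4 against 1602 CPM, ratio 129 [35.5 to 1065]. At 4 Gy 1 cell held 3302 of their 7537 Scgb1a1 UMIs, and 3 of the 35 cells stood above 20000 CPM and 7 above 2000 CPM. Of 591 Scgb3a2 UMIs 292 lay in 1 cell. Cyp2f2 stood at 766 against 2039 CPM, ratio 2.66 [2.20 to 3.25], or 6.15 and 21.5 UMIs per cell. The 10 leading genes of both ciliated clusters include the club markers Scgb1a1, Cyp2f2 and Cbr2, so club cells within this class are not excluded. The club-secreted list had a median log2 ratio of 3.01 [2.68 to 3.39] with 14 of 18 higher and 0 lower by at least 1.5-fold. The p53 list had a median of 0.62 [0.31 to 0.96] there. Alveolar type II-like cells (55 and 23 cells) had a share of 0.966% against 0.552%, ratio 0.572 [0.335 to 0.946], with Scgb1a1 at 428 against 303 CPM, ratio 0.709 [0.536 to 0.928] and Cdkn1a at 2.12 [1.52 to 2.95]. Of their Scgb1a1 UMIs, 106 of 207 at 0 Gy and 44 of 74 at 4 Gy lay in 1 cell. Cdkn1a also had ratios of 2.48 [1.89 to 3.27] in fibroblast-like and 3.55 [2.43 to 5.25] in pericyte- and smooth-muscle-like cells.

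Beyond Per3 and Tef, further clock genes differed in endothelial-like cells. Of 11 genes that peak in the evening in mouse tissues, 10 had a ratio with an interval above 1, and their sum stood at 210.3 against 878 CPM, ratio 4.17 [3.97 to 4.39]. Dbp stood at 4.38 against 43.7 CPM, ratio 9.97 [7.18 to 14.2], Per2 at 0.766 against 24.9 CPM, ratio 32.4 [15.5 to 81.7] and Nr1d1, a repressor of the clock, at a ratio of 4.29 [3.72 to 4.95], while Ciart was at 0.985 [0.874 to 1.11]. Of 5 genes that peak in the morning, 2 had an interval below 1, Arntl, the core activator of the clock (chromosome 7, 113207465 to 113314126, plus strand; 17.8 against 1.46 CPM, ratio 0.0816 [0.0413 to 0.146]), and Nfil3 (0.170 [0.0590 to 0.405]), while Cry1 was higher (3.20 [2.17 to 4.81]). A sum of 4 glucocorticoid-induced genes stood at 641 against 1254 CPM, ratio 1.95 [1.89 to 2.02], with Tsc22d3 at 1.89 [1.76 to 2.03] and Fkbp5 at 3.26 [2.49 to 4.32]. In aerocyte-like cells Arntl had a ratio of 0.312 [0.0759 to 0.967], or at most 0.618 in thinned cells.

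A set of genes with pseudogenes or close relatives moved together in the CD45-positive libraries. Over the 8 CD45-positive classes compared, Olfr77 (2.12 to 3.17) and Tpt1-ps3 (1.21 to 1.75) had a ratio above 1 beyond counting error in 8. H3f3a (0.670 to 0.883), Myl12b (0.572 to 0.715) and Ptma (0.647 to 0.831) had one below 1 in 8, and Tpt1 (0.701 to 0.912) in 7. In the 3 CD45-negative classes H3f3a was also below 1 in 3 (0.527 to 0.865) and Myl12b in 1, while Tpt1 was above 1 in 3, Tpt1-ps3 above 1 in 1, Olfr77 below 1 in 1, and Ptma neither in any. The sum of Tpt1 and Tpt1-ps3 stood at 0.896 to 1.20 in CD45-positive classes.

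The first pattern is the higher level of p53 targets in endothelial-like cells. Depth per cell is argued against, as the median log2 ratio was 1.497 (1.38 to 1.61) in cells thinned to the same number of UMIs. A shift of the scale by a few abundant genes is argued against by a median of 0.027 over 15802 other genes. A different mix of clusters as the whole cause is argued against by the lowest median over the endothelial clusters, 0.73 (0.55 to 1.23) in cluster 20. The dose itself may account for the pattern, as a hypothesis that 1 library per dose leaves untested, along with any other difference between the pools of mice.

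The next pattern is the shift of clock genes in the same cells. Depth is argued against by an Arntl ratio of 0.0465 (0.00940 to 0.141) in thinned cells, and a different mix of clusters as the whole cause by one of 0.0880 (0.0179 to 0.262) within cluster 1. A harvest at another time of day remains open: Arntl had a ratio of 0.955 (0.822 to 1.11) in CD45-positive cells, but evening genes were also higher in CD45-negative cells outside both endothelial classes (2.45, 2.23 to 2.69). These values come from different genes in different sorts, so they cannot be set against each other directly. The dose and the time of day cannot be told apart here, because the labels give no time of day and each dose has 1 library. An effect of the dose on the endothelial clock may be a further explanation. This is a hypothesis that was not tested, and deciding it needs replicate lungs of both doses taken at the same time of day.

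The last pattern is the higher level of Scgb1a1 outside club-like cells. Depth is argued against by a ratio of 9.59 (6.79 to 13.9) in endothelial-like cells thinned to the same number of UMIs. Free RNA from lysed club cells would give each class alike UMIs per cell. Relative to endothelial-like cells the ratio at 4 Gy was 0.984 (0.727 to 1.31) in aerocyte-like, 0.915 (0.296 to 2.15) in pericyte- and smooth-muscle-like and 1.64 (0.911 to 2.72) in tumour-epithelial-like cells, but 4.82 (3.17 to 7.03) in fibroblast-like cells. Fibroblast-like cells also stood above endothelial-like cells at 0 Gy, at 0.346 against 0.0192 UMIs per cell. They were deeper as well, with medians of 15377 against 1974 UMIs at 4 Gy. Their excess is thus no feature of the 4 Gy library alone. The pericyte- and smooth-muscle-like value rests on 5 UMIs. Free RNA and expression in these cells cannot be told apart by this test, in which 3 classes go with free RNA and 1 does not. It sets levels at 4 Gy side by side and not the rise from 0 Gy, which is the pattern. UMIs per cell were 0.0192 at 0 Gy and 0.176 at 4 Gy in endothelial-like and 0.0295 and 0.173 in aerocyte-like cells. They were 0 and 0.161 in pericyte- and smooth-muscle-like, 0.139 and 0.288 in tumour-epithelial-like and 0.346 and 0.848 in fibroblast-like cells. The rise itself was not tested. An effect of the dose on club cells, the subject of the series, may also be the source. This is a hypothesis that was not tested, and deciding it needs replicate libraries with a measure of free RNA, such as empty droplets, at each dose.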
